A study of Nematostella vectensis with 52 samples.

How the data were processed

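Gene expression was measured by tag-based RNA sequencing in 52 libraries from adult starlet sea anemones, Nematostella vectensis, each made from RNA of whole animals. Per the labels' protocols, animals were kept by a published culture method, RNA was extracted with the Ambion RNAqueous kit, and libraries were prepared by the method of Meyer and colleagues, which sequences short fragments near the 3' end of each transcript. Such a method gives about 1 tag per transcript, so gene length has little part in the counts. Reads were aligned with Bowtie2, per the submitters' processing notes, and the labels name the genome assembly of Putnam and colleagues. The Bowtie2 version, the counting tool, any read filter and any removal of duplicate reads are not given in the sources used here.

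The deposited table holds raw counts, whole numbers of tags per gene model, for 23754 gene models with NVE identifiers in 52 columns. No normalization was applied to the deposited counts, whose column totals differ. Each column name matched a line in the description of 1 library, and every column was used. The 52 libraries fall into 14 groups by location and temperature as the labels give them. The reference table used here, of assembly jaNemVect1.1, paired 0 of the NVE identifiers with a name. Genes are therefore given by identifier, with no coordinates, and with at most 2 that rose and 2 that fell in each comparison. For the same reason the 24 gene lists fixed before the data were examined had no members that could be found, and their set tests were void.

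Total counts ran from 159492 to 666007 per library, with a median of 347712.5 and 19535212 in all. At the median total, a gene at 10 CPM (counts scaled to a common library total) is seen fewer than 4 times in a library, so low genes carry large counting error. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. No 2 libraries of a group held identical counts, and in the 72 pairs within groups the chi-square per degree of freedom of the counts ran from 1.32 to 10.27. The lowest was between ME 28 °C replicates A and B, which had 5.45 and 5.92 with replicate D. All 52 libraries were kept as separate samples, although counts that differ do not show that libraries are independent. The labels give a replicate letter for each library and do not say whether replicates were separate animals, so p-values measure the spread between these samples.

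Genes with too few counts were removed with edgeR's filterByExpr on the 14 groups (minimum count 10, minimum total 15), which left 6768 genes and 93.83% of all counts. Counts were scaled by the trimmed mean of M-values (TMM). Every comparison was a contrast in a single fit with 1 coefficient for each of the 14 groups, by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, so that all groups shared the estimate of spread. A gene was called when its Benjamini-Hochberg adjusted p over the 6768 genes was under 0.05. The comparisons were 30 °C against 20 °C averaged over 5 locations and in each location, 28 °C or 32 °C against 20 °C and against 30 °C where a location had them, the 5 locations at 20 °C, each location against the mean of the other 4 at 20 °C, and the interaction of location and temperature. The standard error of a log2 fold change was its size divided by the square root of F. Shares of variation came from PERMANOVA in vegan 2.7.1, with location, temperature and their interaction in that order, on Euclidean distances of log2 CPM with a prior count of 2, over the 38 libraries at 20 °C and 30 °C and 9999 permutations.

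CPM values are mean ± SD over libraries, on TMM-scaled totals. Where every library of a group had 0 counts, the fold is a lower bound set at 3 counts over that group. With 1 to 3 counts over the group, the ratio of summed counts is given with its exact 95% interval, and no fitted fold is used. The named genes were chosen by a fixed rule among called genes at or above the median abundance: the largest fold changes in each direction with the same sign in all 5 locations (average), or with no overlap between the groups compared (single comparisons), and the smallest p for F tests.

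Alternatives fixed in advance were DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, relative log expression (RLE) size factors, no filter on low counts, a stricter filter (10 counts in a share of at least 0.5 of the libraries), only the groups compared in the fit, the replicate letter as a block, and leaving out each library in turn. Chosen after seeing the data were thinning of every library to the smallest total, log2 total count as a covariate, abundance-dependent loess offsets (span 0.3), leaving out the 10 most abundant genes, and leaving out 3 libraries that stood apart from their groups. The fit was tested on simulated counts with 200 of 6768 genes changed. For the average over 5 locations it recovered 77% of genes changed 2-fold and 98% of those changed 4-fold. For MA at 30 °C against 20 °C these were 20% and 72%, for ME 17% and 72%, for SC 21% and 66%, and for ME at 30 °C against 28 °C 17% and 65%. With genes changed only in SC 20 °C, the location test recovered 12% and 62%. With genes changed only in SC 30 °C, the interaction test recovered 2% and 36%. False calls made up from 0% of calls (interaction) to 5.91% (average). Simulated means grew in proportion to depth, so the simulation does not bear on effects of depth.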

Results

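Adult starlet sea anemones (Nematostella vectensis), small cnidarians that live buried in estuarine mud, were collected at 5 locations on the Atlantic coast of North America and held for long periods at different temperatures. The locations were Nova Scotia (NS), Maine (ME), Massachusetts (MA), North Carolina (NC) and South Carolina (SC). Libraries from whole animals were made at 20 °C and 30 °C for all 5 locations, at 28 °C for ME and NS, and at 32 °C for NC and SC. There were 4 libraries per group, except 3 each for ME 28 °C, ME 30 °C, NC 30 °C and NS 28 °C. The design asks how expression responds to warm conditions in each location and how the locations differ. CPM values below are mean ± SD, log2 fold changes are ± SE, and adjusted p is from edgeR's quasi-likelihood test.

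Sequencing depth differed between groups and in part followed temperature. Mean total counts in units of 1000 were 232 ± 10.1 in NS 20 °C, 583 ± 96.3 in NS 28 °C and 279.8 ± 13.9 in NS 30 °C. In ME they were 375 ± 31.6 at 20 °C, 477 ± 7.73 at 28 °C and 425 ± 72.9 at 30 °C, and in MA 339.8 ± 35.2 at 20 °C and 292 ± 97.2 at 30 °C. NC libraries had 264 ± 24.7 at 20 °C, 278 ± 77.8 at 30 °C and 410.1 ± 70.995 at 32 °C. SC libraries had 280.5 ± 47.4 at 20 °C, 520.5 ± 94.9 at 30 °C and 567 ± 67.3 at 32 °C. The 10 most abundant genes took a median of 32.2% of counts at 20 °C, 19.6% at 28 °C, 26.8% at 30 °C and 17.6% at 32 °C. Every library of NS 28 °C, NS 30 °C, ME 28 °C, NC 32 °C, SC 30 °C and SC 32 °C was deeper than every 20 °C library of its location, so depth and temperature are confounded there.

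**Figure D1:**
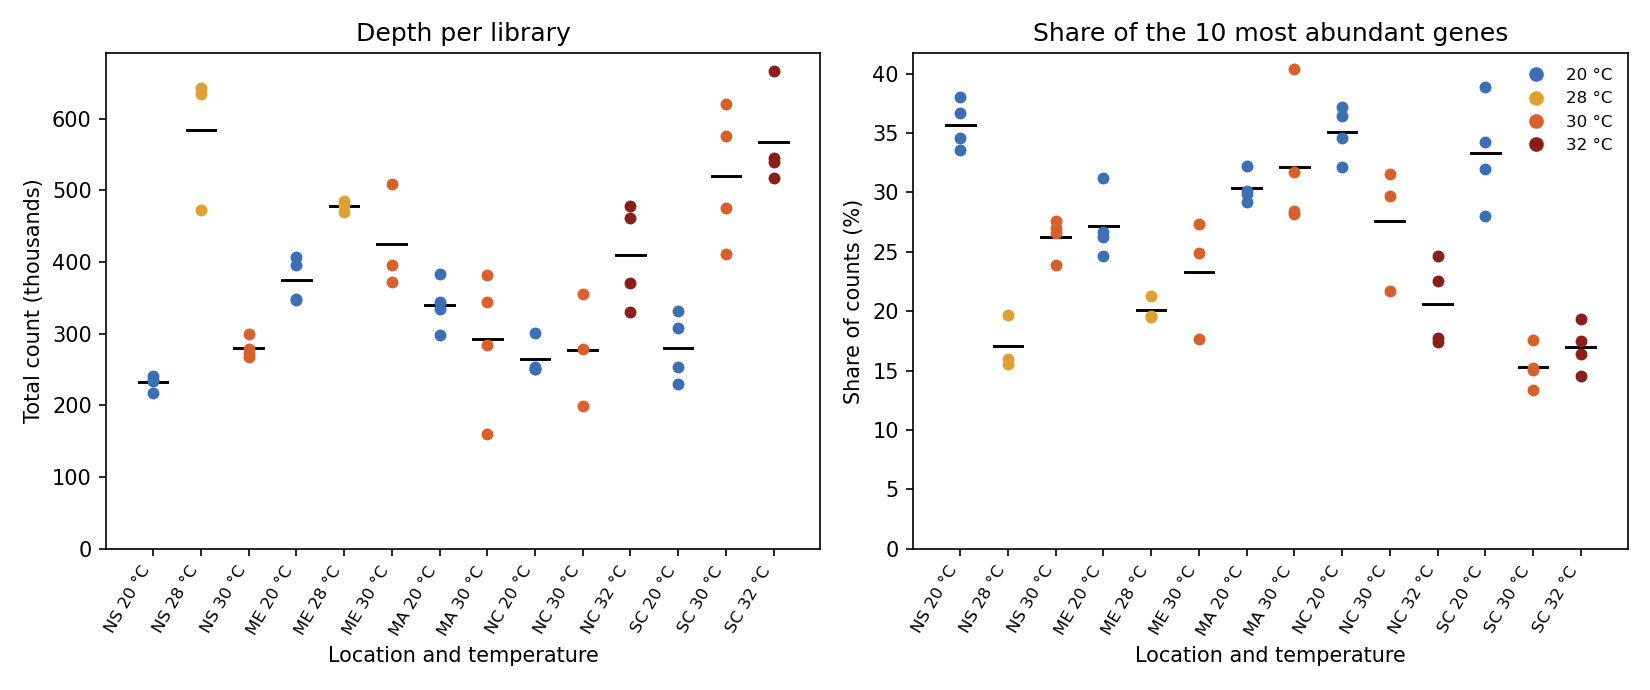
Total counts per library for the 14 groups of location and temperature, with each point a library and the bar the group mean. Totals run from 159492 in MA 30 °C replicate C to 666007 in SC 32 °C replicate B.

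Location accounted for 29.2% of the variation in log2 CPM over the 38 libraries at 20 °C and 30 °C, and temperature for 10.7% (distance-based permutation test, p = 1e-04 for each, the smallest that the permutations can give). Their interaction accounted for 10.1% (permutation p = 0.0051). That p was 0.0052 with RLE size factors, 0.0146 with a prior count of 0.5 and 0.0303 with Spearman distances. Leaving out each library in turn gave 0.001 to 0.009. Location and the interaction have more degrees of freedom than temperature, so the shares do not rank the terms by strength. The F values, which divide by the degrees of freedom, were 4.097 for location, 5.995 for temperature and 1.418 for the interaction. F also grows with the number of libraries at each level of a term, which is larger for temperature. The F values therefore do not rank the terms by strength either. The first principal component held 14.8% of the variance over all 52 libraries and the next 12.0%. Replicates C of NC 30 °C and B of NC 32 °C lay at -21.02 and -16.29 on the latter, and the other NC libraries between 7.15 and 32.79.

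**Figure D2:**
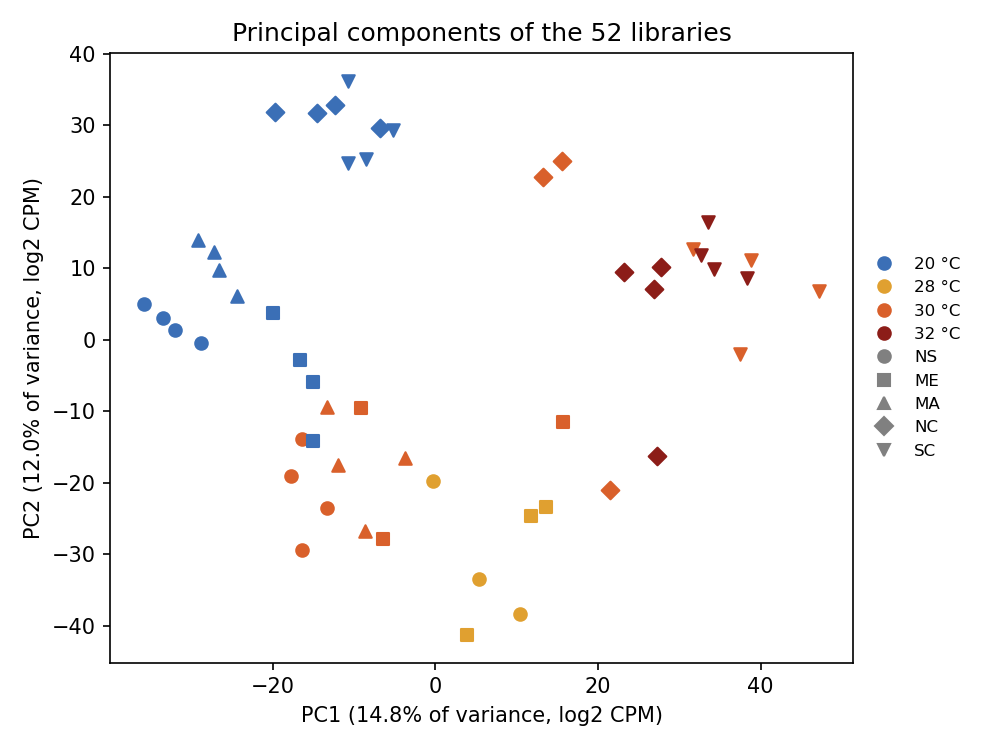
The 52 libraries on principal components 1 and 2 of log2 CPM, with 14.8% and 12.0% of the variance on the axes, marked by location and temperature. NC libraries at 30 °C and 32 °C are spread along component 2, where replicate C of NC 30 °C and replicate B of NC 32 °C lie below 0.

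Averaged over the 5 locations, NVE19335 and NVE253 fell at 30 °C. NVE19335 changed by -2.70 ± 0.25 on the log2 scale (edgeR adjusted p = 1.73e-11), from 252 ± 60.8 to 29.1 ± 18.4 CPM in NS, 209 ± 57.3 to 60.04 ± 38.99 in ME, 371 ± 57.9 to 69.9 ± 80.2 in MA, 247 ± 137 to 6.49 ± 6.16 in NC and 114 ± 79.1 to 47.0 ± 12.0 in SC. NVE253 changed by -2.48 ± 0.33 (edgeR adjusted p = 1.56e-07), for example from 162 ± 37.5 to 21.5 ± 7.79 CPM in NS and from 79.1 ± 30.9 to 21.9 ± 17.3 in SC. NVE20499 and NVE18479 rose (edgeR adjusted p = 8.32e-06 and 2.86e-05). NVE20499 went from 0 to 207 ± 134.1 CPM in NS, from 5.196 ± 4.57 to 487 ± 289.5 in MA, from 23.2 ± 32.1 to 150.2 ± 216 in ME and from 7.83 ± 11.9 to 64.5 ± 121 in SC. In NC 30 °C, NVE20499 and NVE18479 were at 386 and 437 CPM in replicate C and at 0 in replicates A and B. The rise of NVE20499 in SC also came mostly from 1 library, with 246 CPM in SC 30 °C replicate B and 0 to 12.6 in the others. At 32 °C NVE20499 was at 1.75 ± 3.49 CPM in SC and 113 ± 226 in NC. All 4 genes had the sign of the average in each of the 5 locations, as their choice required.

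Across all genes, 1931 of 6768 were called for the average, 999 higher and 932 lower at 30 °C, and 481 of them differed over 2-fold. The split ran from 1334 higher and 787 lower with no filter, 1151 and 829 with RLE size factors and 1132 and 811 with DESeq2 to 673 and 725 with the depth covariate and 843 and 922 with limma voom. Of the 1931, 1295 (67.1%) had the same sign in 5 locations and 578 in 4. For genes called on the average of the other 4 locations, the sign was the same in the location left out for 80.4% of 1827 genes in NS, 84.2% of 1795 in ME, 86.8% of 1662 in MA, 87.2% of 1525 in NC and 78.5% of 1403 in SC. Over all 6768 genes those shares were 65.6%, 67.9%, 69.4%, 69.6% and 64.6%. Of the 10 most abundant genes, 9 were called lower and 0 higher, with a median log2 change of -0.58. The calls of NVE19335 and NVE253 held under every alternative. Those of NVE20499 and NVE18479 ended without NC 30 °C replicate C, alone or with the other libraries that stood apart, with an adjusted p of up to 0.99997 for each, the highest over their alternatives, since the NC 30 °C group is then all at 0. Over the 4 other locations NVE18479 had an edgeR adjusted p of 0.000536.

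**Figure D3:**
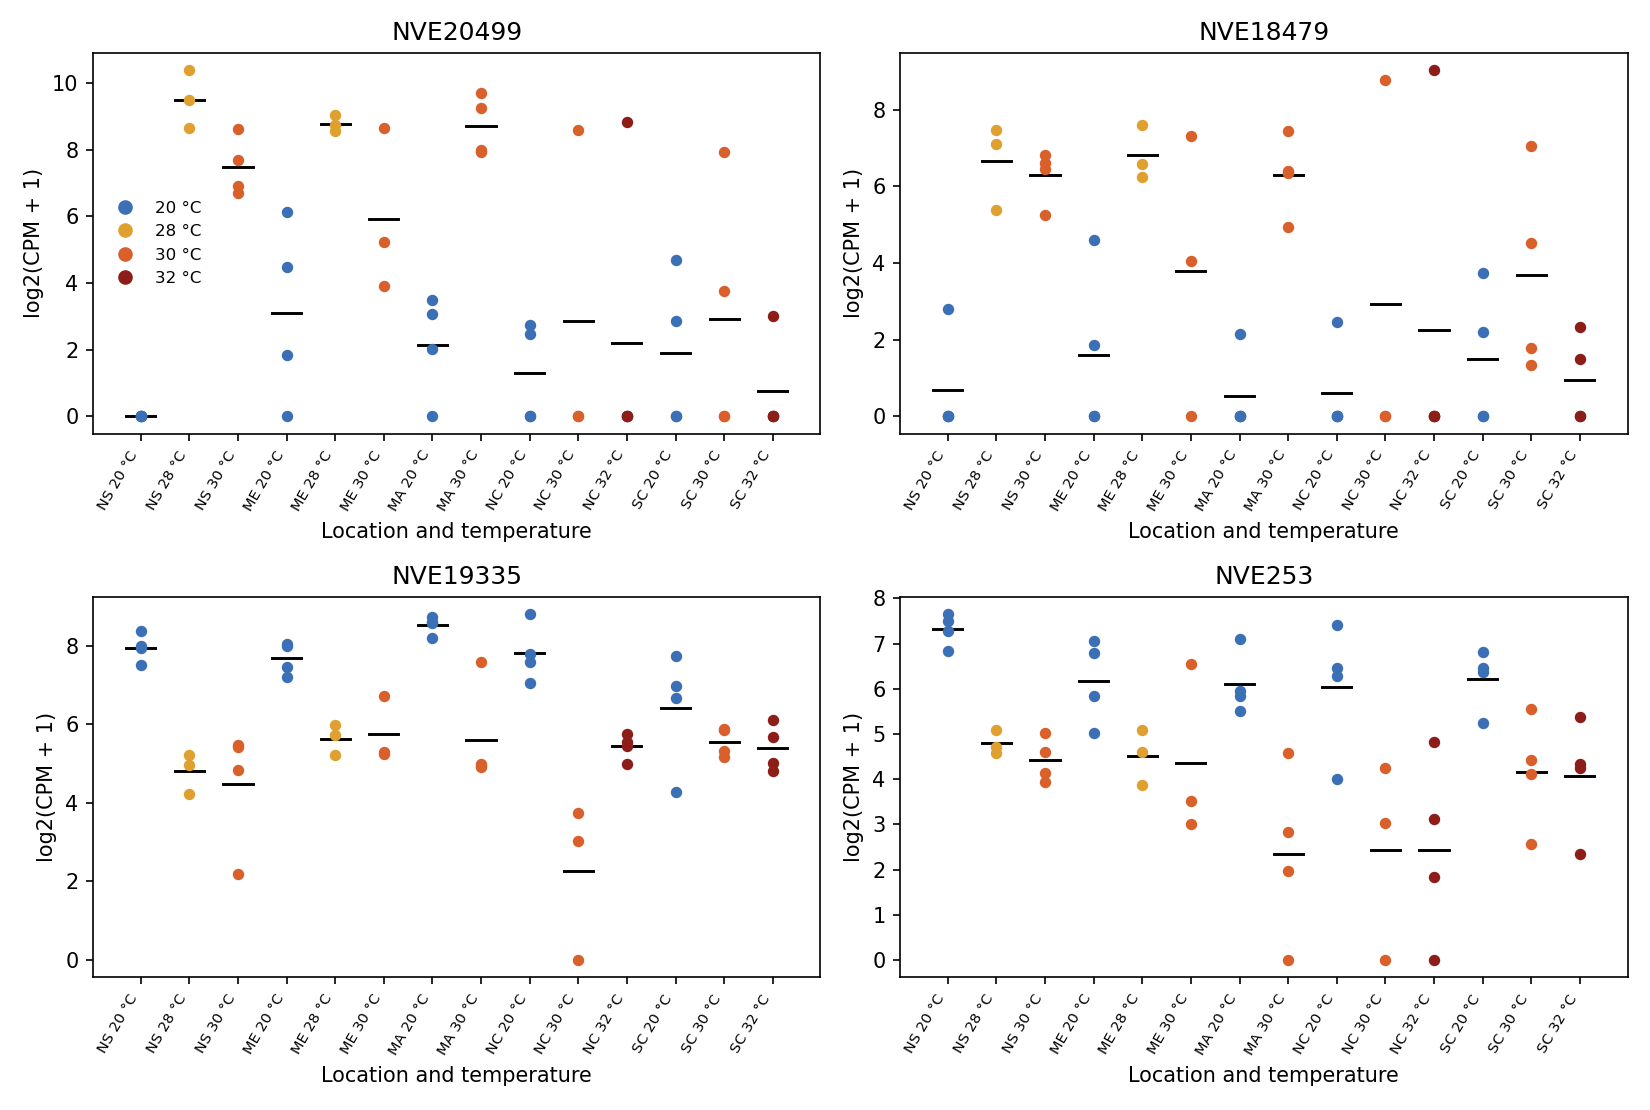
log2(CPM + 1) of NVE20499, NVE18479, NVE19335 and NVE253 in every library, by location and temperature, with the mean of each group as a bar. NVE19335 and NVE253 have lower means at 30 °C than at 20 °C in all 5 locations, and the 30 °C and 32 °C levels of NVE20499 and NVE18479 in NC come from 1 library each.

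In MA, NVE19845 had 0 counts in all 4 libraries at 20 °C and 58.4 ± 34.5 CPM at 30 °C (n = 4), at least 26.0-fold higher (edgeR adjusted p = 0.0194). NVE20499 rose by 6.45 ± 1.59 on the log2 scale (edgeR adjusted p = 0.0166). NVE253 went from 74.8 ± 41.9 to 7.96 ± 10.2 CPM, a log2 change of -3.04 ± 0.82 (edgeR adjusted p = 0.0300), and NVE8689 from 62.6 ± 81.4 to 3.89 ± 3.60, a change of -3.59 ± 0.999 (edgeR adjusted p = 0.0367). For each of the 4 genes every library at 1 temperature lay on the same side of every library at the other, as their choice required. In all, 182 genes were called, 79 higher and 103 lower, of which 155 had no overlap between the groups. Higher calls were instead the more numerous with RLE size factors (94 and 90), a fit of only these groups (130 and 68), DESeq2, limma voom, either other filter and without the 3 libraries that stood apart. Of all genes 9.93% had none, where chance gives 2.86%. Without MA 20 °C replicate A, C or D the count was 63.2%, 45.6% and 57.1% of that in turn, and without MA 30 °C replicate A or C it was 41.2% and 63.7%. The calls of NVE19845 and NVE20499 ended without MA 20 °C replicate A, C or D or MA 30 °C replicate A (highest adjusted p over their alternatives 0.0757 and 0.0714). That of NVE8689 ended without MA 20 °C replicate D (0.341, its highest, with 184 CPM in that library) or any MA 30 °C replicate (0.0679 to 0.124), and that of NVE253 without MA 20 °C replicate A or C or MA 30 °C replicate A, C or D (up to 0.125). Both also ended under limma voom (0.146 and 0.0730), and that of NVE8689 after thinning (0.0608) and without the 3 libraries that stood apart (0.0511).

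In ME, NVE1706 and NVE4720 fell at 30 °C, from 189.9 ± 53.2 to 29.7 ± 11.9 CPM and from 284 ± 63.7 to 51.01 ± 22.4 (n = 4 and 3), with log2 changes of -2.63 ± 0.38 and -2.47 ± 0.41 (edgeR adjusted p = 5.77e-05 and 0.000414). NVE4826 rose from 18.6 ± 5.18 to 81.3 ± 16.5 CPM, by 2.09 ± 0.51 (edgeR adjusted p = 0.0490), and NVE7494 from 35.8 ± 11.4 to 106.9 ± 24.4, by 1.57 ± 0.34 (edgeR adjusted p = 0.0173). The groups did not overlap for any of the 4, as their choice required. In all, 23 genes were called, 11 higher and 12 lower (166 and 46 with no filter, 15 and 11 with RLE size factors, 41 and 34 with DESeq2, 1 and 7 without ME 30 °C replicate A, 1 and 8 without ME 20 °C replicate C), 22 of them without overlap; 10.2% of all genes had none, where chance gives 5.71%. The count was 13, 9 and 15 without ME 20 °C replicates A, C and D, and 8, 13 and 10 without ME 30 °C replicates A, B and C. The calls of NVE1706 and NVE4720 held under every alternative. That of NVE4826 ended with the replicate letter as a block (adjusted p 0.0609) and without any 1 library of ME 20 °C or ME 30 °C (adjusted p 0.0750 to 0.139), and after thinning (0.147, its highest). That of NVE7494 ended without ME 20 °C replicate A, C or D or ME 30 °C replicate A or C (0.0595 to 0.139), in a fit of only these groups (0.0528) and after thinning (0.157, its highest).

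In NC, NVE19335 went from 247 ± 137 to 6.49 ± 6.16 CPM at 30 °C (n = 4 and 3), a log2 change of -5.03 ± 0.74 (edgeR adjusted p = 4.77e-05). NVE10958 went from 1497 ± 1190.3 to 11.7 ± 6.68 CPM, a change of -7.18 ± 1.11 (edgeR adjusted p = 0.000102). NVE25705 was at 204 ± 324 CPM at 30 °C and 5.95 ± 5.66 at 20 °C, higher by 5.07 ± 1.24 (edgeR adjusted p = 0.0134), with 578 CPM in replicate C and 16.3 and 18.1 in A and B. NVE2064 had 58 counts at 30 °C and 3 at 20 °C, a ratio of 18.5 with a 95% interval of 6.03 to 92.4 (edgeR adjusted p = 0.0210). None of the 4 had overlap between the groups, as their choice required. In all, 295 genes were called, 130 higher and 165 lower. RLE size factors gave 164 higher and 135 lower, and loess offsets 150 higher of 274. Of the 295, 230 had no overlap, as had 12.0% of all genes, where chance gives 5.71%. The count was 173 without NC 20 °C replicate A and 48.1% of the 295 without B, 69 without NC 30 °C replicate C, and 80 without the 3 libraries that stood apart. With limma voom it was 96, and with a fit of only these groups 12. The call of NVE19335 held under every alternative and that of NVE10958 ended under limma voom (adjusted p 0.0923). Those of NVE25705 and NVE2064 ended without NC 30 °C replicate C (0.818 and 0.224, the highest over their alternatives), and that of NVE2064 also without NC 20 °C replicate A, B or D (0.0567 to 0.0684). Both also ended under limma voom (0.505 and 0.159), in a fit of only these groups (0.0968 and 0.0555) and without the 3 libraries that stood apart (0.750 and 0.222), and that of NVE2064 after thinning (0.142).

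In NS, NVE19335 went from 252 ± 60.8 to 29.1 ± 18.4 CPM at 30 °C (n = 4 and 4), a log2 change of -3.10 ± 0.53 (edgeR adjusted p = 0.000545). NVE18973 went from 118.4 ± 54.7 to 11.4 ± 8.71, a change of -3.36 ± 0.72 (edgeR adjusted p = 0.00712). NVE25705 rose from 13.3 ± 5.42 to 204 ± 92.5 CPM, by 3.91 ± 1.09 (edgeR adjusted p = 0.0484), and NVE6616 from 22.3 ± 21.1 to 145 ± 44.3, by 2.66 ± 0.64 (edgeR adjusted p = 0.0205). The groups did not overlap for any of the 4, as their choice required. In all, 106 genes were called, 38 higher and 68 lower (254 and 212 in a fit of only these groups), 96.2% of them without overlap; 12.5% of all genes had none, where chance gives 2.86%. The count was 62, 63, 39 and 62 without NS 20 °C replicates A, B, C and D in turn, and 58, 55, 42 and 58 without NS 30 °C replicates A, B, C and D. The call of NVE19335 held under every alternative, and that of NVE18973 ended without NS 20 °C replicate C (adjusted p 0.0517, its highest). That of NVE6616 ended without NS 20 °C replicate A or B or NS 30 °C replicate C or D (up to 0.0864, its highest), and that of NVE25705 without any 1 of the 8 libraries (0.0532 to 0.132, its highest). That of NVE25705 also ended with RLE size factors (0.0527), after thinning (0.0515), without the 10 most abundant genes (0.0513) and with the depth covariate (0.0975, log2 change 3.56 ± 1.11, about as large).

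In SC, NVE25706 had 0 counts in all 4 libraries at 20 °C and 31.9 ± 28.4 CPM at 30 °C (n = 4), at least 8.60-fold higher (edgeR adjusted p = 0.00107). NVE23947 had 162 counts at 30 °C and 2 at 20 °C, a ratio of 33.2 with a 95% interval of 9.03 to 276 (edgeR adjusted p = 0.00102). NVE418 went from 1050.3 ± 390.5 to 141.1 ± 88.9 CPM, a log2 change of -2.90 ± 0.70 (edgeR adjusted p = 0.00257), and NVE24065 from 37.6 ± 25.2 to 6.26 ± 5.67, a change of -2.57 ± 0.90 (edgeR adjusted p = 0.0372). All 4 were free of overlap between the groups, as their choice required. In all, 1345 genes were called, 696 higher and 649 lower (977 and 349 with no filter, 738 and 601 with RLE size factors, 760 and 785 with limma voom, 434 and 454 without SC 20 °C replicate C, 486 and 514 without D), of which 995 differed over 2-fold and 1070 had no overlap; 23.5% of all genes had none, where chance gives 2.86%. The count was 888 without SC 20 °C replicate C, 620 after thinning to the smallest total and 225 with log2 total count as a covariate. With that covariate NVE418 and NVE24065 had log2 changes of -2.15 ± 0.87 and -1.12 ± 0.95 and adjusted p of 0.159 and 0.543, the highest over their alternatives. The calls of NVE25706 and NVE23947 held under every alternative, and that of NVE24065 also ended without SC 20 °C replicate A, B or C or SC 30 °C replicate B, C or D (0.0538 to 0.149), under limma voom (0.0506) and after thinning (0.0984).

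At 28 °C in ME, NVE16216 fell from 113 ± 29.6 to 7.78 ± 4.12 CPM relative to 20 °C (n = 4 and 3), with a log2 change of -3.83 ± 0.63 (edgeR adjusted p = 0.000285). NVE647 went from 439 ± 222 to 75.2 ± 22.4 CPM, a change of -2.54 ± 0.62 (edgeR adjusted p = 0.0146). NVE17218 rose from 4.97 ± 4.88 to 130.3 ± 94.8 CPM, by 4.66 ± 1.33 (edgeR adjusted p = 0.0438), and NVE25705 from 22.99 ± 23.5 to 246 ± 127, by 3.41 ± 0.90 (edgeR adjusted p = 0.0265). The groups did not overlap for any of the 4, as their choice required. In all, 191 genes were called, 69 higher and 122 lower (96 higher of 204 with RLE size factors, 265 higher and 96 lower with no filter), 184 of them without overlap; 17.7% of all genes had none, where chance gives 5.71%. The count was 75 without ME 20 °C replicate D, 88 and 67 without ME 28 °C replicates A and B, 56.5% of the 191 without D, and 94 with the depth covariate. The call of NVE16216 held under every alternative. Calls ended for NVE17218 without any 1 of the 7 libraries (adjusted p 0.0565 to 0.196, its highest), for NVE25705 without ME 20 °C replicate B, C or D or ME 28 °C replicate D (0.0602 to 0.123, its highest) and for NVE647 without ME 20 °C replicate D or any ME 28 °C replicate (0.0520 to 0.0861, its highest). That of NVE17218 also ended under DESeq2 (0.0628), with loess offsets (0.0579) and with the depth covariate (0.171, log2 change 3.91 ± 1.43), and that of NVE25705 after thinning (0.0556) and with the covariate (0.102, 2.94 ± 0.94).

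At 28 °C in NS, NVE20499 and NVE17218 had 817 ± 477 and 148 ± 108.7 CPM (n = 3) and 0 counts in all 4 libraries at 20 °C, at least 217-fold and 40.8-fold higher (edgeR adjusted p = 0.00304 and 0.0163). NVE19335 went from 252 ± 60.8 to 28.0 ± 9.48 CPM, a log2 change of -3.13 ± 0.53 (edgeR adjusted p = 8.09e-05), and NVE1253 from 95.7 ± 19.7 to 15.5 ± 5.16, a change of -2.63 ± 0.61 (edgeR adjusted p = 0.00437). For none of the 4 did the groups overlap, as their choice required. In all, 630 genes were called, 290 higher and 340 lower (483 and 161 with no filter, 316 and 294 with RLE size factors, 328 and 294 with loess offsets, 590 and 777 with limma voom), 571 of them without overlap; 24.0% of all genes had none, where chance gives 5.71%. The count was 363 without NS 20 °C replicate B, 366 and 245 without NS 28 °C replicates A and B, and 8 with the depth covariate. There the adjusted p of NVE20499, NVE17218, NVE19335 and NVE1253 was 0.276, 0.748, 0.199 and 0.328, the highest over their alternatives. The log2 changes of NVE19335 and NVE1253 were then -2.79 ± 0.88 and -3.06 ± 1.16, of similar size with larger errors, as depth and temperature are confounded in these groups. For NVE20499 and NVE17218 no fitted change is given, because they had 0 counts at 20 °C. The call of NVE17218 also ended without NS 28 °C replicate B (0.0717).

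At 32 °C in NC, NVE2064 had 521 counts and at 20 °C 3 (n = 4 and 4), a ratio of 74.3 with a 95% interval of 25.3 to 361 (edgeR adjusted p = 2.52e-06). NVE20814 had 68 counts against 2, a ratio of 14.5 with an interval of 3.87 to 122.5 (edgeR adjusted p = 0.0154). NVE23459 went from 1885 ± 1261 to 52.9 ± 91.3 CPM, a log2 change of -5.09 ± 1.15 (edgeR adjusted p = 0.00193), and NVE2933 from 131.02 ± 107.7 to 5.78 ± 6.001, a change of -4.65 ± 1.04 (edgeR adjusted p = 0.00177). The groups did not overlap for any of the 4, as their choice required. In all, 884 genes were called, 410 higher and 474 lower (620 and 333 with no filter, 480 and 412 with RLE size factors, 420 and 378 with loess offsets, 395 and 373 without NC 32 °C replicate B), 589 of them without overlap; 13.3% of all genes had none, where chance gives 2.86%. A fit of only these groups called 228, limma voom 549 and the fit with the depth covariate 342. The call of NVE2064 held under every alternative, and those of NVE23459 and NVE2933 ended under limma voom (adjusted p 0.191 and 0.134, their highest). That of NVE20814 ended without NC 20 °C replicate A or B or NC 32 °C replicate A (0.0529 to 0.0598), under limma voom (0.1297), in a fit of only these groups (0.0764), after thinning (0.1097) and with the depth covariate (0.133, its highest).

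At 32 °C in SC, NVE25706 had 50.3 ± 14.3 CPM and 0 counts in all 4 libraries at 20 °C (n = 4), at least 15.1-fold higher (edgeR adjusted p = 9.14e-05). NVE25341 had 254 counts against 2, a ratio of 46.8 with a 95% interval of 12.8 to 389 (edgeR adjusted p = 4.15e-06). NVE21584 went from 50.6 ± 26.2 to 2.98 ± 2.68 CPM, a log2 change of -3.92 ± 0.65 (edgeR adjusted p = 2.32e-05), and NVE23787 from 53.9 ± 52.4 to 3.88 ± 4.55, a change of -3.72 ± 1.31 (edgeR adjusted p = 0.0448). Groups were apart for each of the 4, as their choice required. In all, 1068 genes were called, 559 higher and 509 lower (729 and 277 with no filter, 617 and 483 with RLE size factors, 678 and 727 with limma voom), 886 of them without overlap; 21.96% of all genes had none, where chance gives 2.86%. With the depth covariate the count was 12.4% of that, and after thinning 516. Calls of NVE25706, NVE25341 and NVE21584 held under every alternative, while that of NVE23787 ended with the replicate block (adjusted p 0.0581) and without SC 20 °C replicate C or D or any SC 32 °C replicate (0.0519 to 0.243), under limma voom (0.117), after thinning (0.206) and with the depth covariate (0.325, its highest; log2 change -3.63 ± 1.81).

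The upper temperatures of a location were also compared with each other. In NS, NVE13796 went from 146 ± 39.99 CPM at 28 °C to 11.6 ± 8.46 at 30 °C (n = 3 and 4), a log2 change of -3.56 ± 0.68 (edgeR adjusted p = 0.00499), and NVE4653 from 64.3 ± 40.2 to 7.67 ± 3.68, a change of -3.07 ± 0.76 (edgeR adjusted p = 0.0279). NVE24466 rose by 2.17 ± 0.55 (edgeR adjusted p = 0.0300) and NVE8266 by 1.98 ± 0.52 (edgeR adjusted p = 0.0347), to 39.6 ± 21.4 and 380.4 ± 155 CPM. In all, 122 genes were called, 58 higher and 64 lower (47 and 91 with loess offsets, 344 and 281 with limma voom, 26 and 19 after thinning), 96.7% of them without overlap; 17.9% of all genes had none, where chance gives 5.71%. With the depth covariate edgeR called 0 genes (463 at an unadjusted p under 0.05; without it DESeq2 called 183 and limma voom 625). The adjusted p of NVE24466, NVE8266, NVE13796 and NVE4653 was then 0.713, 0.651, 0.771 and 0.882, their highest. Log2 changes in the same order were 1.63 ± 0.75, 1.89 ± 0.72, -1.77 ± 0.98 and -1.22 ± 1.004, so that of NVE8266 stayed about as large with a larger error, and those of NVE13796 and NVE4653 shrank. The count was 11 and 4 without NS 28 °C replicates A and B and 38, 53, 62 and 45 without NS 30 °C replicates A, B, C and D. Calls ended for NVE24466 without NS 28 °C replicate A or B or NS 30 °C replicate C or D (0.0723 to 0.201), for NVE8266 without any NS 28 °C replicate or NS 30 °C replicate A, B or D (0.0510 to 0.122) and for NVE4653 without NS 28 °C replicate A or B or any NS 30 °C replicate (0.0575 to 0.166).

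In ME at 30 °C against 28 °C (n = 3 and 3), edgeR called 0 genes, with 343 at an unadjusted p under 0.05 where chance gives 338, and a smallest adjusted p of 0.201. DESeq2 and limma voom also called 0, with 309 and 502 at an unadjusted p under 0.05. Without ME 30 °C replicate A the count was 1.

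In NC at 32 °C against 30 °C (n = 4 and 3), NVE8455 went from 221 ± 90.8 to 33.7 ± 7.48 CPM, a log2 change of -2.69 ± 0.37 (edgeR adjusted p = 2.29e-05), and NVE16216 from 99.3 ± 62.3 to 18.6 ± 11.9, a change of -2.45 ± 0.56 (edgeR adjusted p = 0.0286). NVE6210 rose from 4.33 ± 4.11 to 45.0 ± 14.4 CPM, by 3.12 ± 0.62 (edgeR adjusted p = 0.00795), and NVE13226 from 9.15 ± 2.58 to 58.1 ± 28.7, by 2.68 ± 0.54 (edgeR adjusted p = 0.00857). In all, 43 genes were called, 20 higher and 23 lower (19 and 15 with loess offsets), 36 of them without overlap. Of all genes 7.18% had none, where chance gives 5.71%. At least as many genes were called in 16 of 35 splits of these libraries, the real one included. A fit of only these groups called 0 genes in edgeR (374 at an unadjusted p under 0.05; over all groups DESeq2 called 71 and limma voom 20). There the adjusted p of NVE8455 was 0.2299 and that of the other 3 genes 0.758, the highest over their alternatives. The count was 18, 9 and 89 without NC 30 °C replicates A, B and C and 28, 120 and 12 without NC 32 °C replicates A, B and C. Calls ended for NVE6210 without NC 30 °C replicate B (0.0576) and for NVE16216 without NC 30 °C replicate A or B or NC 32 °C replicate A or C (0.0590 to 0.232). Those of NVE6210, NVE13226 and NVE16216 ended under limma voom (0.209, 0.204 and 0.104), those of NVE13226 and NVE16216 after thinning (0.0733 and 0.0501), and that of NVE16216 with the depth covariate (0.215, log2 change -2.01 ± 0.63).

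In SC at 32 °C against 30 °C (n = 4 and 4), NVE1706 fell from 57.3 ± 12.9 to 10.5 ± 4.85 CPM, with a log2 change of -2.40 ± 0.38 (edgeR adjusted p = 0.000144), and NVE24408 went from 298 ± 305 to 47.6 ± 33.7, a change of -2.61 ± 0.62 (edgeR adjusted p = 0.0377). NVE7457 rose from 31.4 ± 25.6 to 157 ± 88.4 CPM, by 2.38 ± 0.44 (edgeR adjusted p = 0.00185), and NVE25341 from 21.1 ± 6.80 to 103 ± 25.8, by 2.27 ± 0.46 (edgeR adjusted p = 0.00644). In all, 29 genes were called, 8 higher and 21 lower, 27 of them without overlap; 6.19% of all genes had none, where chance gives 2.86%. The count was 12 without SC 30 °C replicate B and 15 and 18 without SC 32 °C replicates A and C. The call of NVE1706 held under every alternative, and those of NVE7457 and NVE25341 ended after thinning (adjusted p 0.0569 and 0.105; the highest for NVE7457 was 0.135, with only these groups). That of NVE24408 ended with the replicate block (0.0525), with the depth covariate (0.0634, log2 change -2.51 ± 0.64, about as large), in a fit of only these groups (0.146) and without SC 30 °C replicate B (0.468, its highest) or SC 32 °C replicate A, C or D (0.118 to 0.184).

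**Figure D4:**
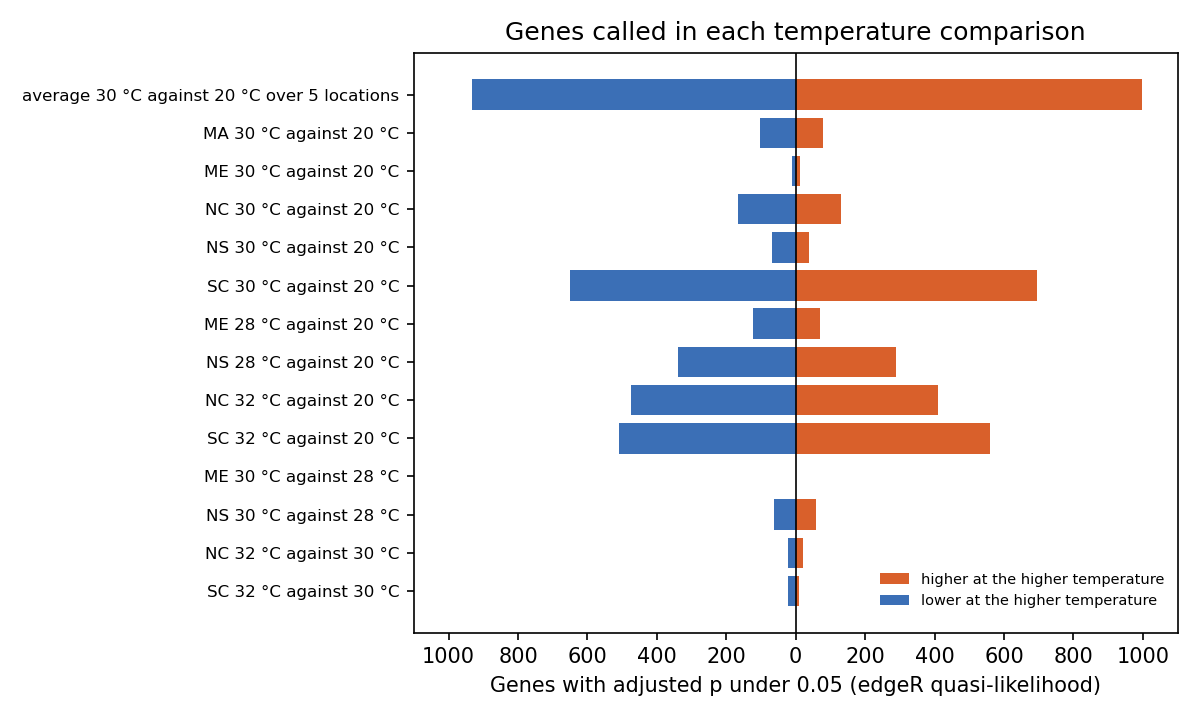
Number of genes called higher and lower (edgeR adjusted p under 0.05) in each temperature comparison. The average over 5 locations has 999 higher and 932 lower, SC at 30 °C against 20 °C 696 and 649, and ME at 30 °C against 28 °C has no bar.

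The locations differed at 20 °C. NVE24510 stood at 4143 ± 1954 CPM in NS, 2095 ± 1114 in ME and 1666 ± 1461 in MA, and at 1.14 ± 2.28 in NC and 2.45 ± 3.02 in SC. NVE6609 had 0 counts in all 4 NS libraries, 63.6 ± 15.3 CPM in ME, 249.7 ± 56.7 in MA, 399 ± 200.3 in NC and 396 ± 53.9 in SC. The location F test of edgeR gave an adjusted p of 1.42e-14 for each, and both calls held under every alternative. In all, 799 of 6768 genes were called.

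Against the mean of the other 4 locations (n = 4 in each), NS had 186 genes called, 112 higher and 74 lower. NVE19300 was at 156 ± 39.9 CPM in NS and 0, 11.1 ± 22.2, 0 and 11.9 ± 8.63 in ME, MA, NC and SC (edgeR adjusted p = 4.30e-07), and NVE7408 at 112 ± 5.91 in NS, 36.6 ± 14.4 in ME, 66.1 ± 34.9 in MA, 54.3 ± 28.3 in NC and 0 in SC (edgeR adjusted p = 0.000109). NVE1757 and NVE6609 had 0 counts in NS and were at least 58.3-fold and 62.1-fold lower there (edgeR adjusted p = 4.51e-13 for each). Without NS 20 °C replicates A, B, C and D in turn the count was 57.0%, 61.8%, 64.0% and 62.9% of that.

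ME had 373 genes called against the other 4 locations, 245 higher and 128 lower. NVE18600 was at 287 ± 47.4 CPM in ME, 32.5 ± 24.95 in MA, 6.11 ± 5.64 in NC, 4.51 ± 5.41 in SC and 0 in NS (edgeR adjusted p = 3.76e-15). NVE5522 was higher by 2.74 ± 0.27 (edgeR adjusted p = 4.76e-10), and the log2 differences of NVE1825 and NVE17831 were -2.95 ± 0.43 and -2.75 ± 0.39 (edgeR adjusted p = 3.33e-06 and 2.30e-06). The count was 192 and 218 without ME 20 °C replicates A and B, and 154 with the depth covariate.

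MA had 151 genes called, 111 higher and 40 lower. NVE491 and NVE10179 were at 527 ± 248 and 755 ± 398 CPM in MA, higher than the other 4 by 2.98 ± 0.36 and 2.96 ± 0.38 on the log2 scale (edgeR adjusted p = 1.69e-07 and 6.22e-07). NVE23717 and NVE14622 were at 41.8 ± 36.5 and 57.2 ± 50.3 CPM, differences of -2.92 ± 0.50 and -2.88 ± 0.37 (edgeR adjusted p = 0.000157 and 5.46e-07). The count was 99, 82 and 95 without MA 20 °C replicates B, C and D.

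NC had 257 genes called, 183 higher and 74 lower. NVE1757 was at 383 ± 111 CPM in NC, 163 ± 66.2 in ME, 231 ± 42.0 in MA, 218 ± 46.4 in SC and 0 in NS (edgeR adjusted p = 1.27e-09), and the 0 in NS lowers the mean that NC is set against. NVE14792 was at 404 ± 148, higher by 3.18 ± 0.42 (edgeR adjusted p = 5.60e-07). NVE18617 had 0 counts in NC and was at least 80.1-fold lower (edgeR adjusted p = 2.27e-06), and NVE6194 was at 6.06 ± 4.56 CPM, a difference of -4.60 ± 0.56 (edgeR adjusted p = 1.47e-07). Without NC 20 °C replicate C the count was 166.

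SC had 225 genes called, 61.8% of them higher and 86 lower. NVE538 was at 109.9 ± 44.4 CPM in SC and between 0 in NS and 15.1 ± 7.31 in ME elsewhere (edgeR adjusted p = 2.21e-06), and NVE7733 was at 78.8 ± 19.8, higher by 1.52 ± 0.35 (edgeR adjusted p = 0.00509). NVE17046 and NVE12007 had 0 counts in SC and were at least 36.5-fold and 22.3-fold lower (edgeR adjusted p = 0.000192 and 3.11e-06). The count was 62.7% and 51.6% of that without SC 20 °C replicates B and D, and the call of NVE7733 ended without replicate B (adjusted p 0.0577) and after thinning (0.0666, its highest). Of the 20 named results of single locations, the libraries of that location did not overlap the other 16 for any gene, as their choice required. NVE7733 was the only one of the 20 whose call ended under an alternative. Of all called genes, 39 of 186 in NS, 40 of 373 in ME and 19 of 151 in MA had no overlap. In NC these were 37 of 257 and in SC 30 of 225. Of all genes 0.296% (MA) to 0.813% (NS) had none, where chance gives 0.0413%.

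The change from 20 °C to 30 °C differed between locations for 144 genes (edgeR interaction F test). NVE18925 changed by -2.41 ± 0.23 in NC and -1.42 ± 0.20 in SC on the log2 scale, with -0.08 ± 0.19 in NS, -0.33 ± 0.20 in ME and -0.09 ± 0.18 in MA (edgeR adjusted p = 6.02e-07). NVE7851 went from 219 ± 129.9 to 739 ± 122.5 CPM in SC and from 639 ± 128 to 249 ± 81.0 in NC, log2 changes of 1.78 ± 0.28 and -1.35 ± 0.30, with -0.25 ± 0.29 in NS, -0.39 ± 0.30 in ME and -0.39 ± 0.28 in MA (edgeR adjusted p = 4.75e-05). Both calls held under every alternative. Of the 144 genes, 83 were also called on the average over locations, and 29 had the same sign in all 5. The largest change in size lay in SC for 70.1% of them, in NC for 18, in NS for 15, in MA for 8 and in ME for 2. The count was 74 without SC 20 °C replicate A, 71 without SC 30 °C replicate C, and 13 with the depth covariate.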

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

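The splits of the samples were planned, and the tests of depth, library number, mislabelling and gene programs below were chosen after the results were seen. A search for 1 library far from the other 3 of its group covered 169 groups of 4, over total counts, genes detected, the share of the 10 most abundant genes, and the named genes in the groups compared. Gene groups with under 40 counts were not searched. It found 15, where chance alone marks about 1 in 20 groups, 8.45 here.

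NC 20 °C replicate C had a total of 301.07 in units of 1000 counts, and the others of its group 250.4 to 254. MA 30 °C replicate C had 9516 genes detected, and the others 14206 to 14981. SC 30 °C replicate B had 246 CPM of NVE20499 and 133.01 of NVE18479, where the others had 0 to 12.6 and 1.53 to 22.1. NVE19335 was at 190.1 CPM in MA 30 °C replicate B and 29.0 to 30.7 in the others. NVE8689 was at 184 CPM in MA 20 °C replicate D and 14.8 to 30.6 in the others. NVE7494 was at 52.9 CPM in ME 20 °C replicate B and 28.8 to 30.8 in the others. NVE23459 was at 189.7 CPM in NC 32 °C replicate A and 3.39 to 12.9 in the others. NVE24408 was at 97.8 CPM in SC 32 °C replicate B against 28.0 to 35.5, and at 755 in SC 30 °C replicate B against 128 to 164. NVE6609 was at 166 CPM in MA 20 °C replicate D and 266 to 285 in the others. NVE10179 was at 260.3 CPM in SC 20 °C replicate A and 21.5 to 43.4 in the others. NVE23717 was at 537 CPM in NC 20 °C replicate C and 242 to 260.1 in the others. SC 20 °C replicate B had 43.4 CPM of NVE538, against 130.2 to 133.3, and 108.4 of NVE7733, against 68.2 to 70.4.

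The change from 20 °C to 30 °C differed between locations for 144 genes in the interaction F test of edgeR. Among 100 splits only 1, the real one, gave as many, and the highest other gave 44. These splits exchanged location labels within a temperature, which mixes libraries of locations that differ at 20 °C. They therefore cannot decide whether chance gave the interaction count. Of the named genes, NVE18925 and NVE7851 had interaction adjusted p of 6.02e-07 and 4.75e-05. NVE10958 had 0.00130, with a log2 change of -7.18 ± 1.11 in NC and 1.11 ± 0.63 in MA. NVE7494 had 0.0426, with 3.17 ± 0.34 in SC and 1.25 to 1.57 in the other 4 locations.

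SC had 1345 genes called at 30 °C and ME 23. Library depth as the whole cause was argued against: the ratio of SC to ME counts was 62 after thinning and 13.2 with the depth covariate. The 3 libraries of ME 30 °C were also argued against as the cause, since the lowest SC count without 1 of its 30 °C libraries was 935. Against MA, NC and NS depth and location cannot be told apart, because SC had 4.56 times the highest of their counts after thinning and 0.804 times with the covariate (225 against 242 in MA and 280 in NC). A direct test of the difference between SC and ME called 92 genes. As many were called in 8 of 100 splits, the real one included, and the highest gave 494. These splits exchanged SC and ME labels within a temperature, so general differences between SC and ME enter their contrasts. They therefore cannot decide whether chance gave the count.

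NC 30 °C replicate C and NC 32 °C replicate B lay apart from the other NC libraries. Low depth was argued against, as 0 of the 2 had the lowest total of its group, and so was a label of the wrong location. A wrong temperature or replicate label and a mixed library were not tested. Over 41 genes that mark locations at 20 °C, the highest correlation of the 2 across genes with NS, ME or MA was -0.129. Their correlation with SC less that with NC was at most 0.00109, against at least 0.375 in the 8 heated SC libraries. In the other heated NC libraries it ran from -0.587 to 0.0437. NC 32 °C replicate B still correlated slightly better with SC (0.5496) than with NC (0.5486), as did NC 30 °C replicate B and NC 32 °C replicate D. These genes thus set heated NC libraries poorly apart from SC, and 29 of 32 heated libraries correlated best with their own location. Within the heated groups of the other 4 locations (25 libraries), the 88 genes high in these 2 varied together (median pairwise correlation 0.533, random lists -0.004 to 0.045), as did the 29 genes low in them (0.480, random lists -0.032 to 0.056). A candidate explanation is therefore genes that vary together between libraries of a heated group, in NC as elsewhere. The mean log2 CPM of the 88 lay above the highest 20 °C library of the location, by over the SD of its 20 °C libraries, in 7 of 7 heated libraries in NS, 4 of 4 in MA, 4 of 6 in ME, 3 of 7 in NC and 2 of 8 in SC. In NC 30 °C replicates A and B it was 3.56 and 3.44, below the 3.61 to 3.70 of NC 20 °C. On the average over the 4 locations other than NC, which had no part in choosing the genes, 42 of the 88 and 2 of the 29 were called higher (11.3% of all genes were). Whether the gene sets are opposed, as in animals of different sex or reproductive state, stays open. Their median correlation with each other was -0.161 (random lists -0.013 to 0.041), but 8 of the 25 libraries lay above their 20 °C libraries in both sets. The mean of the 29 stayed between 4.39 and 4.57 in the heated NS libraries. The labels give neither sex nor the number of animals in a library. NVE20499, NVE18479, NVE17218, NVE25705 and NVE13796 belong to the 88 genes.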

How the results depend on the processing

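Thinning, the depth covariate, loess offsets, leaving out the 10 most abundant genes and leaving out the 3 libraries that stood apart were chosen after seeing the data; the others were planned. The named genes gave 76 results, of which 37 stayed past the threshold under every alternative run. Of 1917 values under alternatives, 1744 kept sign and call, 173 kept the sign and lost the call, and 0 reversed. Most lost calls came from leaving out 1 library, 17 from the depth covariate, 14 from thinning, 13 from limma voom and 10 from a fit of only the groups compared. Counts not given here were within 1.5 times the number first reported.

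Thinning every library to the smallest total lowered counts because fewer tags remain. It gave 1254 for the average, 82 for MA, 10 for ME, 136 for NC, 55 for NS and 620 for SC at 30 °C against 20 °C. It gave 63 for ME and 280 for NS at 28 °C, 430 for NC and 516 for SC at 32 °C, 45 for NS at 30 °C against 28 °C, and 16 for SC at 32 °C against 30 °C. The rest were 504 for the location F test, 201 for ME, 83 for MA and 136 for SC against the other locations, and 59 for the interaction. Depth therefore limits how many genes are called. With log2 total count as a covariate the counts were 225 for SC at 30 °C, 94 for ME and 8 for NS at 28 °C, and 342 for NC and 1.3e+02 (12.4% of the number first reported) for SC at 32 °C. They were 0 for NS at 30 °C against 28 °C (edgeR, 463 at an unadjusted p under 0.05; DESeq2 183 and limma voom 625 without the covariate), 6 for NC at 32 °C against 30 °C, 154 for ME against the other locations and 13 for the interaction. For all other changes the cause was not tested.

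With no filter on low counts the counts were 336 for MA, 212 for ME and 224 for NS at 30 °C, 361 for ME at 28 °C, 12 for ME at 30 °C against 28 °C, and 174 for NC and 185 for SC at 32 °C against 30 °C. There were 337 for NS, 602 for ME, 280 for MA, 432 for NC and 386 for SC against the other locations, and 369 for the interaction. The stricter filter gave 1264 for the average, 44 for ME at 30 °C, and 95 for MA and 1.4e+02 for SC (63.1% of the number first reported) against the other locations. DESeq2 gave 75 for ME and 171 for NS at 30 °C, 71 for NC and 50 for SC at 32 °C against 30 °C, and 264 for the interaction. limma voom gave 96 for NC and 349 for NS at 30 °C, 569 for ME and 1367 for NS at 28 °C, and 549 for NC at 32 °C. It gave 625 for NS at 30 °C against 28 °C, 20 for NC and 74 for SC at 32 °C against 30 °C, 1272 for the location F test, 335 for NS against the other locations and 237 for the interaction. A fit of only the groups compared gave 12 for NC and 466 for NS at 30 °C, 997 for NS at 28 °C, and 228 for NC at 32 °C. It gave 265 for NS at 30 °C against 28 °C, 0 for NC (edgeR, 374 at an unadjusted p under 0.05; over all groups DESeq2 71 and limma voom 20) and 11 for SC at 32 °C against 30 °C. Without the 3 libraries that stood apart there were 80 for NC at 30 °C, 364 for ME at 28 °C and 185 for NS at 30 °C against 28 °C. RLE size factors, loess offsets and leaving out the 10 most abundant genes moved no count by over 1.5 times.

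Leaving out each library in turn gave 1633 to 1956 genes for the average, 75 to 187 for MA, 8 to 19 for ME, 69 to 438 for NC, 39 to 63 for NS and 888 to 1244 for SC at 30 °C, 67 to 177 for ME and 245 to 598 for NS at 28 °C, and 594 to 837 for NC and 748 to 1013 for SC at 32 °C. It gave 0 to 1 for ME and 4 to 85 for NS at 30 °C against 28 °C, 9 to 120 for NC and and 12 to 29 for SC at 32 °C against 30 °C. There were 661 to 775 for the location F test, 106 to 195 for NS, 192 to 390 for ME, 82 to 148 for MA, 166 to 259 for NC and 1.2e+02 (51.6% of the number first reported) to 238 for SC against the other locations, and 71 to 201 for the interaction. The libraries that move a count by over 1.5 times are named beside each result. The share of variation ran from 28.9% to 30.7% for location and from 10.3% to 11.2% for temperature, and with Spearman distances it was 37.1% and 16.2%.

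The replicate letter as a block gave 1901 genes for the average, 190 for MA, 16 for ME, 273 for NC, 90 for NS and 1315 for SC at 30 °C, 224 for ME and 643 for NS at 28 °C, and 834 for NC and 1068 for SC at 32 °C. It gave 0 for ME (411 at an unadjusted p under 0.05 in edgeR; DESeq2 and limma voom 0 without the block) and 129 for NS at 30 °C against 28 °C, and 41 for NC and 21 for SC at 32 °C against 30 °C. The others were 781 for the location F test, 182 for NS, 359 for ME, 88.7% of the number first reported for MA, 245 for NC and 220 for SC against the other locations, and 97.9% of the number first reported for the interaction. The letters share no more than a name: correlations of deviations between libraries with the same letter ran from -0.36 to 0.27, and in no comparison were all over 0.1 or did every library correlate best with its own letter, except in NS at 30 °C against 28 °C (3 of 3 pairs best with their own letter). No library fell under the planned minimum total, so that setting gave no value, and the gene list settings were not run because the lists had no members.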

Other observations

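The tests of the abundant genes were chosen after the result was seen; the test of heat genes at 20 °C and the splits were set beforehand, without the intervals of the former, and the heat score was chosen after seeing the data. A score of the heat response was made for each location from genes called on the average of the other 4, as the mean log2 CPM of those higher at 30 °C less that of those lower, relative to the location's own 20 °C mean. It stood at 1.51 ± 0.33 (SD, n = 3) at 28 °C and 0.98 ± 0.14 (n = 4) at 30 °C in NS, at 1.25 ± 0.12 (n = 3) and 0.81 ± 0.28 (n = 3) in ME, and at 1.15 ± 0.20 (n = 4) at 30 °C in MA. In NC it was 1.30 ± 0.45 (n = 3) at 30 °C and 1.46 ± 0.22 (n = 4) at 32 °C, and in SC 1.08 ± 0.20 (n = 4) and 0.98 ± 0.12 (n = 4). Each of the 9 comparisons with 20 °C had an exact permutation p of 0.0286 (two-sided, the smallest possible with 4 against 4 or 3; adjusted p 0.0371 over 13 comparisons). The score was lower at 30 °C than at 28 °C in NS by a difference of -0.53 (exact permutation p = 0.0286, adjusted 0.0371) and in ME by -0.45 (exact p = 0.1, the smallest possible; adjusted 0.118), where the 28 °C libraries were also deeper on average. From 30 °C to 32 °C it differed by 0.17 in NC (exact p = 0.571, adjusted 0.571) and -0.11 in SC (exact p = 0.371, adjusted 0.402). These differences turn on single libraries. In NC it was 0.42 without NC 30 °C replicate C, with all 4 libraries at 32 °C above the other 2 at 30 °C (exact p = 0.0667, the smallest possible), and 0.03, 0.05 and 0.06 without NC 30 °C replicates A and B and NC 32 °C replicate B in turn. In SC it was -0.16, -0.03 and -0.07 without SC 30 °C replicates A, B and C and -0.05 without SC 32 °C replicate D. The ME difference was -0.28 without ME 30 °C replicate A.

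Whether genes that rise with heat already stood higher at 20 °C in the southern locations was tested with genes called higher on the average of the 3 locations outside each pair. The differences in mean log2 CPM were 0.15 for NC less NS, 0.05 for SC less NS, -0.20 for NC less ME and -0.11 for SC less ME (exact permutation p = 0.0571, 0.429, 0.114 and 0.286, adjusted over 10 pairs at least 0.190). The hypothesis needs all 4 above 0. The lowest, -0.203, had a 95% interval of -0.41 to 0.11 by the exact permutation test, and the intervals of the other 3 also included 0. NC less NS lay above the range of random gene lists (-0.04 to 0.08) and NC less ME below its own (-0.12 to -0.01). By the rule set beforehand, any difference at 0 or below counts against the hypothesis, and NC less ME and SC less ME were below 0. The planned prediction was therefore not met. By the intervals, which were added later, the spread of 4 libraries in each location does not settle the sign of any of the 4 differences.

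Of the 10 most abundant genes, 9 were called lower at 30 °C on the average. Within groups, their mean log2 count grew by 0.482 per doubling of the total (95% interval 0.34 to 0.62), against 0.88 for genes of abundance rank 11 to 30 and 1.36 for ranks 301 to 3000. Deeper libraries may therefore show a lower share of these genes without a change in the animals, and the median change of the 10 was 0.10 in MA at 30 °C, where depth was lower (log2 depth ratio -0.28), and -1.58 in SC, where it was higher (0.89). In NC at 30 °C, where depth was about equal (0.04), it was -0.62 with 9 of the 10 lower, which the depth trend does not account for. Depth as the whole cause was argued against, since 9 stayed lower past the threshold with the depth covariate, with a median of -0.40 in place of -0.58. Temperature stays open for the rest, and why the counts of these genes grow slowly was not tested.

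By the planned rule of a share under 0.05, other splits of the same libraries argued against chance for the comparisons listed next. In each, only 1 split, the real one, gave as many genes. They were the average (1931 genes, highest of the other 99 splits 41) and, at 30 °C, MA (182, 25), ME (23, 8), NC (295, 53), NS (106, 1) and SC (1345, 23). The rest were ME (191, 33) and NS (630, 111) at 28 °C, NC (884, 100) and SC (1068, 21) at 32 °C, NS at 30 °C against 28 °C (122, 9) and SC at 32 °C against 30 °C (29, 3). Apart from the average, each had 35 splits, so 1 of 35 was the smallest share possible. No adjustment was made over the comparisons. Chance could also be excluded for the location F test (799, 82). Against the other locations the counts were NS (186, 82), ME (373, 171), MA (151, 45), NC (257, 21) and SC (225, 33). There too only the real split gave as many genes. These splits exchanged libraries among locations, so differences between any of the locations enter their contrasts. They therefore cannot decide whether chance gave the count of a single location. For NC at 32 °C against 30 °C chance could not be excluded: 16 of 35 splits gave at least its 43 genes and the highest 540, which points to structure among the NC libraries. For ME at 30 °C against 28 °C the 10 splits are too few for a share under 0.05 (0 genes in the real split by edgeR, 343 at an unadjusted p under 0.05; 3 in the highest other).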
